A study of Arabidopsis thaliana with 4 samples.

How the data were processed

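Chromatin immunoprecipitation followed by hybridisation to an array (ChIP-chip) was used to measure histone H3 trimethylated at lysine 4 (H3K4me3), a modification found at the 5′ ends of transcribed genes, in Arabidopsis thaliana seedlings of the Col-0 accession. Per the labels, the seedlings were 10 days old, had been grown in liquid medium in long days and had received no treatment. The DNA precipitated with an antibody against H3K4me3 (IP) and the input DNA of the same ChIP replicate were amplified, labelled with Cy3 or Cy5 and hybridised together. The 4 arrays came from 2 ChIP replicates, I and II, each hybridised as a dye-swap pair with IP in Cy5 on one array and in Cy3 on the other. The labels do not say whether replicates I and II were separate cultures, so the spread behind the p-values from limma may be technical. With 2 values per probe, limma takes that spread largely from all probes together and only in part from the probe itself. The permutation p-values rest on shuffles of plates or wells.

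The values analysed were those in the authors' deposited value table, which gives one log ratio per array and probe. They were taken as log2 ratios of the deposited channels, but the log base, the centring and the direction (IP over input or input over IP) are not given in the sources used here, and values are therefore called log units. The normalisation, and the scanner intensities behind it, are also not given in the sources used here. The table had 21800 probes, of which 109 had no value on any array. Of these 109, 70 had plate-and-well IDs and 39 had other IDs, such as reporter genes and controls. The other 21691 probes all had plate-and-well IDs and all entered the analysis. For every one of the 21691 probes the 2 arrays of a dye-swap pair held the same value. The values do not tell whether the pair had been combined or a single array's ratio entered for both. Each pair was counted as 1 replicate, which left n = 2 for every probe. The scanner intensities were not analysed here, so signal over background is unknown, and the number of replicates limits the precision.

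Each replicate was centred on its median over probes, and the mean of the replicates was tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 21691 probes and a threshold of 0.05. "Above" and "below" the median refer to these centred values. The estimated prior degrees of freedom were 10.5. The test was tried on 20 simulated data sets of 21691 probes, with variances drawn from the fitted prior and 200 probes moved by a known amount. It recovered a median of 50% of the moved probes at a shift of 1 log unit (range 12 to 70%) and 100% at shifts of 2, 3 and 4 (at 2, range 98 to 100%). A median of 14.0% of the calls were false (range 3.49 to 34.3%), against 4.95% (2.91 to 8.47%) when the same values were tested with the prior at its true value. With 200 probes moved, the prior degrees of freedom were estimated poorly. Their median was 22.0 (range 8.25 to 1e+06, where estimates were capped), against a true value of 10.5. With 10000 probes moved, nearer to the share called in the data, a median of 3.32% of the calls were false (2.45 to 4.27%) with the prior estimated. The last 2 settings were added after the first had been seen. In all of them the unmoved probes were centred on 0 and the probes were drawn independently of each other. An earlier form of the simulation, which took the variances from the differences between the replicates, recovered none of the moved probes and was replaced. A count of probes with a mean of at least 1 log unit, which needs no variance estimate, was given beside the test.

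Agreement of the replicates was measured across probes with Pearson and Spearman correlations, with a 95% interval for the Pearson correlation from 500 bootstrap draws of plates. Shares carry exact Clopper-Pearson 95% intervals, which treat probes as independent and are too narrow where neighbours are alike. Probe IDs are made of a set (TA, TB, TC, TD or PD), a plate and a well. Comparisons between sets, of probes in ID order and of plates were chosen after the data were examined. They used bootstraps over plates (1000 draws), shuffles within plates (1000), shuffles of the order of plates (10000), permutations of plates (100000) and circular shifts of set labels along the plates (199). Circular shifts were added after the permutation of plates had been seen, because that permutation ignores the likeness of neighbouring plates. A plate was called low where its median was under -0.3 in both replicates, and runs of at least 5 consecutive low plates were taken as stretches; both limits were set after the plate medians had been seen.

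Before the data were examined, tests had been laid down for gene lists, chromosome domains, positions relative to genes, the dye effect, single dye orientations, fits to the 4 separate arrays and the difference between the replicates. The first 3 need a link from probes to genes or coordinates, which was not used here, and no list could be tested. The rest need arrays of one pair to differ. The planned gene lists and domains all lay on chromosome 4, so the shares of probes given below should not be read as shares of the genome. The rule for named probes asked for the 10 highest and 10 lowest means with the same sign in both replicates; without gene names, 2 of each are named and the others are given as a range. Alternatives covered centring (none or on the mode), scale (equal median absolute deviation or quantile normalisation), the variance prior, thresholds, a 2-component Gaussian mixture with a posterior above 0.99 and each replicate alone. Further alternatives chosen after seeing the data removed plate medians or well-parity medians, left out probes whose replicates differed by at least 2 log units or plates TC17 to TC30, fixed the prior degrees of freedom at 4, and used unadjusted p-values. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used for all other steps.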

Results

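H3K4me3 was profiled by ChIP-chip in untreated Col-0 seedlings, with the immunoprecipitated DNA of each of 2 ChIP replicates hybridised against its own input on a pair of dye-swapped arrays. The arrays of a pair held identical values for all 21691 probes with a value, so the 4 arrays gave 2 values per probe. As deposited, the values of replicate I had a median of -1.91 log units and ranged from -4.72 to 3.79, and those of replicate II had a median of -0.90 and ranged from -3.33 to 6.80. Because neither the centring nor the direction of these ratios is given in the sources used here, probes are described as above or below the replicate median and not as enriched or depleted.

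The first comparison asked which probes had an IP and input ratio that differed from the replicate median. Most probes lay close to the median, and a minority formed a long upper tail. Of the 21691 probes, 6033 (27.8%) lay above the median at limma's adjusted threshold, with a median log ratio of 1.63, and 4265 (19.7%) lay below it, with a median of -0.86. The remaining 11393 (52.5%) did not pass. The 95th percentile of the probe means stood 2.55 log units over the 50th, and the 5th percentile stood 1.03 under it. A mean of at least 1 log unit was reached by 4714 probes (21.7%), of which 4706 also passed the test, and 1229 probes (5.67%) had a mean of -1 or less.

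The balance of upper and lower calls depended on where 0 was placed and on the threshold. With median centring 58.6% of the calls lay above 0 (6033 against 4265), with centring on the mode, which lay at -0.23 log units from the median in replicate I and at -0.19 in replicate II, 73.8% did (7273 against 2586), and without centring 6.88% did (915 against 12388). Without centring, the offset between the replicate medians also entered the spread of each probe. The 6.88% therefore does not come from the place of 0 alone. With median centring kept, the share rose to 70.3% at a limma adjusted p under 0.01. It was 79.3% when a size of 1 log unit was required beside the main threshold. In simulations of 21691 probes with 2 replicates, a median of 14.0% of the calls were false when 200 probes were moved and 3.32% when 10000 were. There the unmoved probes were centred on 0, moved probes shifted by at least 1 log unit, and probes were independent. The data have a mode off the median, lower calls with a median of -0.86 and neighbours that are alike. The simulated shares therefore do not give the false share among the calls in the data.

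**Figure D1:**
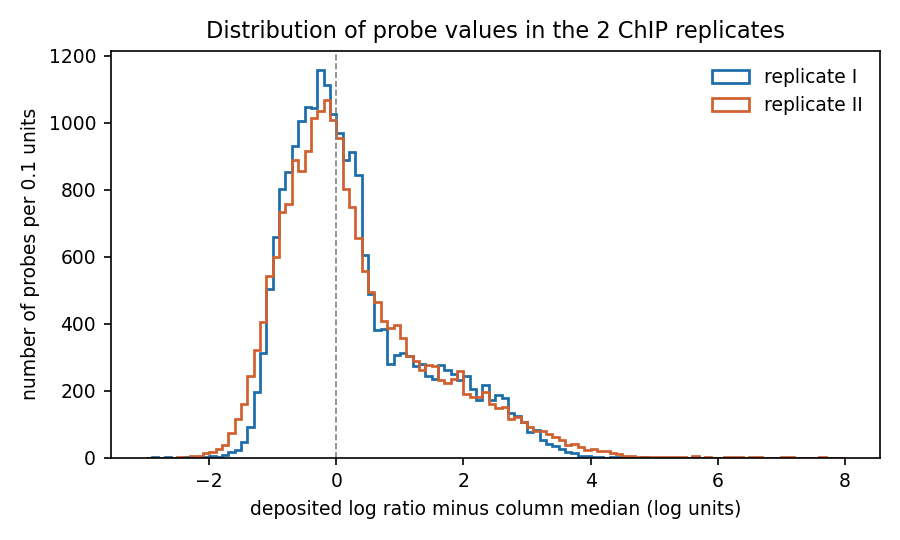
Number of probes (vertical axis, per 0.1 log units) against the deposited log ratio minus the replicate median (horizontal axis, log units), with a line for each of replicates I and II and a dashed line at the median. Both replicates have a long upper tail, and the 95th percentile of the probe means lies 2.55 log units over the 50th.

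Among probes with the same sign in both replicates, a condition of the rule for naming them, TB40E11 had the highest mean, with 5.70 log units in replicate I and 7.05 in replicate II (limma adjusted p = 1.22e-06), followed by TB16A09 with 4.66 and 6.53. Probe TA56G11 had the lowest mean, with -2.81 and -2.11 (limma adjusted p = 8.49e-06), followed by TA06C05 with -2.67 and -2.19. The size of these adjusted p-values rests on the estimated prior. With prior degrees of freedom fixed at 4, the adjusted p of the same kind of test was 0.00153 for TB40E11 and 0.00226 for TA56G11. The 10 highest means ran from 4.53 to 6.37 and the 10 lowest from -2.46 to -1.82. At 3 of the 10 highest the mean was over 1.5 times the value in replicate I alone, and at none of the 10 lowest was it over 1.5 times the value in either replicate. The table does not pair these IDs with genes.

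The second comparison asked how closely the ChIP replicates matched. Across probes, which are not independent replicates, the values of I and II had a Pearson correlation of 0.883 (95% interval 0.877 to 0.890) and a Spearman correlation of 0.826. Both replicates placed 17584 probes (81.1%) on the same side of the median. A value of at least 1 log unit was reached by 4784 probes in replicate I and 4974 in replicate II, and 4068 reached it in both, where independent lists would share 1097. The SD of the difference between replicates was 0.56 log units, and the median size of the difference was 0.33. Values were spread slightly more widely in replicate II (ratio of SDs 1.10). The replicates differed by at least 2 log units at 106 probes, and replicate II was the higher at all 106.

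**Figure D2:**
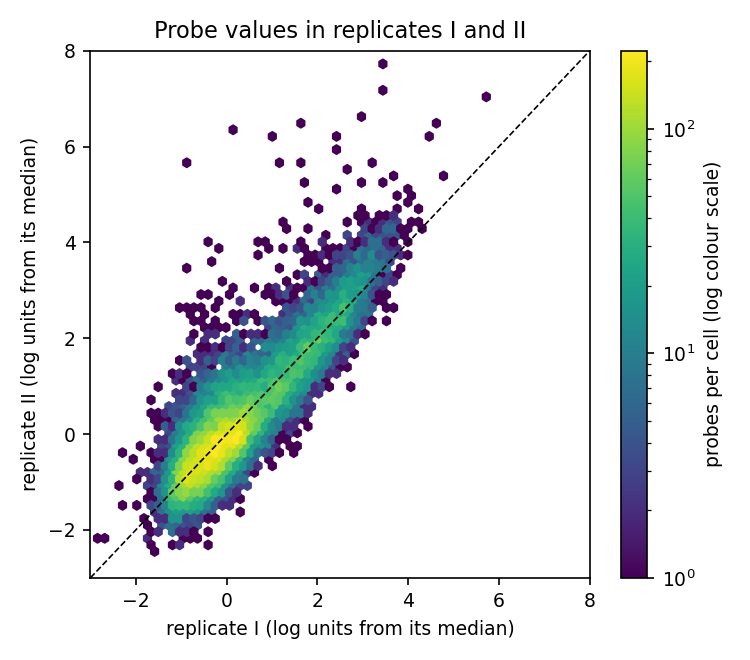
Value of each probe in replicate II (vertical axis) against replicate I (horizontal axis), both in log units from the replicate median, with colour giving the number of probes per cell on a log scale and a dashed line where both are equal. The correlation across probes is 0.883, and the probes farthest from the line lie above it.

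Probe sets, read from the letters of the IDs, differed in their share of high probes. For the largest sets, TA and TB, that difference did not pass a test that keeps the plate order. With median centring, a mean of at least 1 log unit was found for 15.8% of the 9293 TA probes (95% interval 15.1 to 16.6%), 28.5% of the 9581 TB probes (27.6 to 29.4%), 18.2% of the 2406 TC probes (16.7 to 19.8%), 15.6% of the 96 TD probes (9.02 to 24.5%) and 20.3% of the 315 PD probes (16.0 to 25.2%). Without centring the shares were 4.29% for TA, 8.32% for TB, 5.45% for TC, 2.08% for TD and 7.94% for PD. On the lower side, which is the upper side if the ratios are input over IP, the order of the sets differed: with median centring a mean of -1 or less was found for 8.90% of TA, 1.597% of TB, 10.1% of TC, 1.04% of TD and 1.59% of PD probes. Averaged over plates, the TB share exceeded the TA share by 12.8 percentage points. A two-sided permutation of plates gave p = 2e-05, the smallest that 100000 permutations can give, but it treats neighbouring plates as unrelated. When set labels were shifted circularly along the plates, 35 of the 199 shifts, the unshifted labels among them, gave a difference as large (two-sided permutation p = 0.176). The difference in high probes thus did not pass a test that keeps the plate order. That test has little power, since shifts close to each other give almost the same labels. It was not run on the share at -1 or less. The TC set fell into parts. In plates TC00 to TC13, 33.5% of 1282 probes had a mean of at least 1 (31.0 to 36.2%), against 0.712% of 1124 probes in plates TC17 to TC30 (0.308 to 1.40%), and a mean of -1 or less was found for 1.56% and 19.8%. This split was chosen after the values were seen. It lies at a gap in the ID order, since the plates between TC13 and TC17 had no probe with a value.

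Probes with consecutive IDs carried similar values. The correlation of the mean with that of the next probe along a plate row was 0.636 (95% interval 0.619 to 0.652, 19372 pairs), and it was 0.590 (0.504 to 0.671) over the 217 pairs that joined the last well of one plate to the first well of the next. It was 0.34 at a distance of 2 probes, 0.22 at 3 and 0.10 at 960. Vertical neighbours on a plate, which are 12 IDs apart, had a correlation of 0.173 (0.137 to 0.208). The 4635 probes of sets TA, TB and TC with a mean of at least 1 formed 1960 runs, of which 618 held 1 probe, 1010 held 2 or 3 and 332 held 4 or more, up to 12. Shuffling the probes within plates gave 3341 runs on average and never fewer than 3251 in 1000 shuffles.

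High probes were scarce in 3 stretches of plates. The medians of the 226 plates of sets TA, TB and TC ran from -0.90 to 1.17 log units and had a correlation of 0.882 between the replicates. A mean of at least 1 log unit was found for 6.24% of 785 probes in plates TA21 to TA29 (95% interval 4.65 to 8.17%), 1.85% of 1192 probes in TA39 to TA51 (1.16 to 2.78%) and 0.874% of 801 probes in TC17 to TC25 (0.352 to 1.79%), against 24.6% of 18502 probes in the other 195 plates (24.01 to 25.3%). These 195 still held 14 low plates outside the stretches, where 7.88% of 1282 probes reached a mean of 1 (6.46 to 9.49%), against 25.9% of 17220 probes in the 181 plates that were not low (25.2 to 26.5%). The last stretch ends at TC25 because plate TC26 had no probe with a value, and plates TC27 and TC28 were low as well. A mean of -1 or less was found for 18.2%, 24.1% and 23.7% of the probes in these stretches, against 3.26% in the other plates. The stretches were picked as low, so this contrast describes them and does not test them. Shuffles of the plate order asked whether low plates lay together. In the data 31 plates fell into such stretches, against at most 10 in 10000 shuffles (permutation p = 0.0001, the smallest these shuffles can give). Both limits behind the stretches were set after these plate medians had been seen, so this p-value describes the runs and is not an independent test. Wells without a value were more frequent in the stretches, which had 9, 13 and 9 plates, than in the other plates. Plate TA22 held 60 probes with a value and TA39 held 42, and outside the stretches TC13 held 34. These gaps were not examined. With plate medians removed, the shares in the stretches were 10.6%, 4.53% and 3.0%, and without centring they were 2.29%, 0.587% and 0%. The share in TC17 to TC25, which rests on 7 probes, was also 1.75% with centring on the mode and 1.498% without replicate I.

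**Figure D3:**
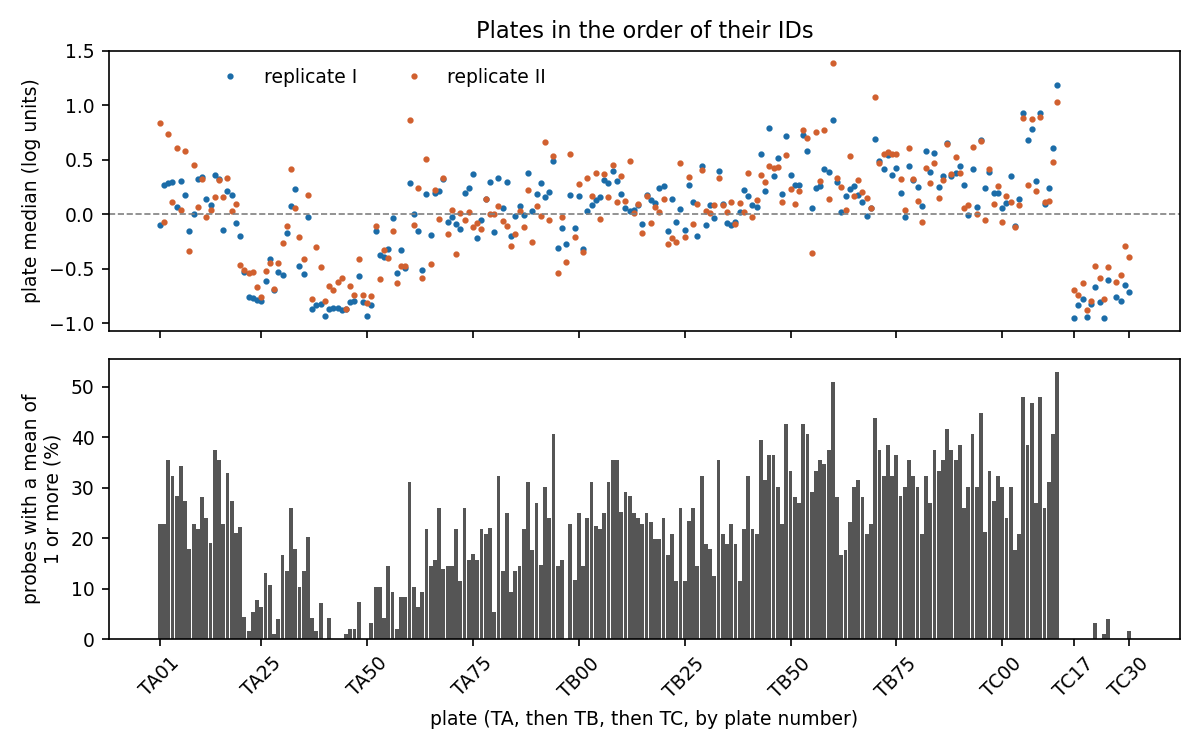
Plate medians of replicates I and II (upper panel, log units) and the percent of probes with a mean of at least 1 log unit per plate (lower panel), with the plates of sets TA, TB and TC in ID order. By the rule that defines them, both replicates are low in the 3 stretches, where the share of high probes is 6.24%, 1.85% and 0.874%.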

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

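The alternatives that removed plate or well-parity medians, left out discordant probes or plates TC17 to TC30, fixed the prior degrees of freedom or dropped the adjustment were chosen after seeing the data. The number of probes above the median moved from 6033 to 915 without centring and 3298 with the mixture, and to 2973 to 3288 with the mixture on a single replicate. The number below moved from 4265 to 12388 without centring, 2586 with centring on the mode, 2135 at an adjusted p under 0.01 and 1229 when a size of 1 log unit was also required. The number with a mean of at least 1 moved from 4714 to 1354 without centring. The shifts without centring follow from its construction, since 0 then lies over both medians. The offset between the replicate medians also enters the spread of each probe in that fit. There, 915 probes passed above 0 although 1354 had a mean of at least 1. A stricter threshold calls fewer probes by construction. The mixture on both replicates was such a stricter cut: it called no mean under 1.52 log units, and 3334 probes had a mean of at least 1.5. For the mixture on a single replicate the cut was not examined. Removing plate medians lowered the correlation of the replicates from 0.883 to 0.872. The other 35 alternatives for these results stayed within 1.5 times the count or within the spread of the value, among them 5427 above and 3222 below with prior degrees of freedom fixed at 4. For named probes, probe sets, stretches and neighbours, 117 alternatives left the value past its threshold or within its interval or spread and 24 moved it outside. Some of the 117 could not move the value. Leaving out plates TC17 to TC30 cannot change the shares of the other sets, and a change of centring cannot change the correlation of neighbours. An interval can be wide: the share in plates TC17 to TC25, 0.874%, stayed inside it at 1.75% with centring on the mode, 1.498% without replicate I and 1.37% with well parity removed. For the 4 named probes, all 44 tested values stayed past the threshold, with limma adjusted p up to 0.00226, and 0 values were reversed. These probes were picked as the extremes of the same data, so this outcome was to be foreseen, and reversal was looked for nowhere else. Alternatives by dye orientation, with the 4 arrays kept apart, and by gene or chromosome position were not run, for the reasons given with the processing. A single replicate has no test. Signal over background was not analysed here.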

Other observations

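Of the tests in this part, only the correlation with the next probe across replicates, the uniform plate offset and the ratio of steps at the edges of the low stretches were written before their results were seen. The others, which include both tests of the correlation across plate ends, were chosen after. No biological explanation was tested, since the design holds a single group and probes were not placed in the genome.

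The direction of the deposited ratios may be IP over input. A mark limited to part of the probed sequence would give the IP ratio a long upper tail. The skewness was 0.974 in replicate I (95% interval 0.923 to 1.03) and 1.04 in replicate II (0.975 to 1.12). This is a hypothesis from the same values, and the tail could also come from the unknown normalisation.

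Neighbouring IDs were alike within and across plates. Likeness of adjacent wells as the whole source is argued against by the plate ends, whose correlation exceeded that of vertical neighbours by 0.417 (95% interval 0.326 to 0.502). Noise of a single hybridisation is argued against by the correlation of 0.582 between replicate I of a probe and replicate II of the next. A candidate explanation is that IDs number fragments in their order along the sequence, for which the correlation of 0.590 across plate ends is needed and was found. An effect of spot position shared by all arrays stays open, since the layout of the spots was not used here.

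The low stretches of plates are not a uniform offset of whole plates. Their 10th percentile lay at -0.55 log units from that of the other plates and their 90th at -2.04, a difference of -1.49 (95% interval -1.72 to -1.32). Whether the level is set plate by plate stays open. Only the 4 edges of the TA stretches could be used, since the plates next to TC17 to TC25 had no probe with a value. There the median step between 12 wells on each side was 4.54 times the median step of the plate medians. By the rule written beforehand, a step between wells as large as that of the plate medians spoke for a level set plate by plate. The ratio met that rule. Single edges ran from 0.177 times at TA51 to TA52, against edges at plate ends, to 617 times at TA38 to TA39. At TA38 to TA39 and TA29 to TA30 the plate medians differed by only 0.0013 and 0.028 log units. Plates TA38 and TA30 missed the low limit in replicate II alone, at -0.298 and -0.267. These edges therefore come from the limit, and the ratio cannot decide the question. In a comparison added after the ratio was seen, 4 of the other 218 plate ends were drawn at random. In 35.0% of such draws the median of their steps was as large as that of the edges. The question was called open only after this comparison. A change of spread per plate was not tested and remains possible, as does a region with little H3K4me3, or with much of it if the ratios are input over IP.

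The difference between the replicates followed the plate in the first plates and the well within plates. Plate medians were higher in replicate II at odd plates from TA01 to TA09 and lower at even plates from TA02 to TA10. They were -0.10 in replicate I and 0.84 in replicate II at TA01, and 0.27 and -0.07 at TA02. The alternation ended at TA11, with 0.34 and 0.32, and was not tested. After removal of plate medians, the medians of the 4 classes of odd or even row and column spanned 0.20 log units in replicate II (permutation p = 0.001, the smallest 1000 shuffles can give) and 0.01 in replicate I (permutation p = 0.399). In I minus II they spanned 0.190, against at most 0.0319 in shuffles (permutation p = 0.001, again the smallest). Position on the plate or array in replicate II is a candidate explanation, and printing and hybridisation cannot be separated here.

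Of the 24 probes with at least 5 log units in replicate II, values in replicate I ran from -0.82 to 5.70 with a median of 3.02. The largest excess of replicate II over replicate I was 6.51 log units, and the largest in the other direction was 1.92.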
